A study of Mus musculus with 8 samples.

How the data were processed

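PolyA RNA sequencing was examined in CD8+ T cells from mouse spleens and lymph nodes, in 2 separate experiments. In the first, cells lacking Trim28 were compared with cells carrying floxed, intact Trim28 after activation in vitro. In the second, cells stimulated with antibodies to CD3 and CD28 for 3 days were compared with and without an antibody against IL-2. Each of the 4 groups had 2 libraries, and the labels do not say whether these came from separate mice, separate cultures or the same RNA. The p-values therefore measure only the spread between these libraries, which may be technical. RNA was extracted with TRIzol and sequenced by BGI.

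Per the submitters' processing notes, the authors used Trim Galore 0.4.4, HISAT2 2.2.1, StringTie 2.1.4 and DESeq2 on the mm10 genome, while the read counter, the annotation and the filters were not stated. The values the authors deposited per library are a normalised signal, namely gene read counts divided by DESeq2 size factors within each experiment. The authors also gave log2 fold changes, coded as reference over treated, and DESeq2 adjusted p-values, which were used here only as a comparison. Whole reads were recovered by dividing each library by the value of 1 read, and 100% of values came out whole within a tolerance of 0.001. Recovered reads per library were 13254136 and 13222831 in the control, 13398371 and 13469789 in the knockout, 16653962 and 16618750 in untreated and 17042931 and 17069569 in blocked cells. The plan had assumed raw counts and an edgeR test with TMM. Because the deposited values were scaled, limma on these values became the reported test. EdgeR with TMM on the recovered reads became an added alternative, beside the planned ones with RLE and upper-quartile scaling.

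The knockout table listed 49490 genes, 24 of them with names altered to dates, and 55291 genes were listed for blockade, with 46556 names in both. Genes with a value of at least 10 in at least 2 libraries were tested, 15415 and 13978. Values were converted to log2 (value + 1), a scale that understates the fold change of weakly expressed genes, and the groups were compared with limma 3.58.1 (moderated test with a mean-variance trend) in R 4.3.3. P-values were adjusted by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Each experiment was fitted alone, and the difference of the 2 effects was tested in a fit of all 8 libraries. Overlaps used Fisher's exact test (two-sided), whose p-values were too small to be represented, so odds ratios are given. Genes sharing reads with copies or pseudogenes have uncertain values, and no strand information was at hand to separate antisense transcripts. Positions and gene types came from the GENCODE mouse annotation on GRCm38.

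Before the data were examined, 33 gene lists and the rule for naming genes were fixed. The lists were IL-2 and STAT5 targets, cytotoxic effector molecules, cytokines and chemokines, naive and memory genes, effector transcription factors, inhibitory receptors and exhaustion, activation markers and nutrient receptors, T cell receptor signalling, the IL-17 programme, Il2 locus neighbours, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid stress response, ribosome biogenesis, DNA replication, mitosis, BCL2 family and death receptors, p53 targets, interferon response, the KAP1 heterochromatin pathway, chromatin loop proteins, imprinted genes, germline genes, immediate early and heat shock genes and mitochondrially encoded genes. Others were markers of B cells, myeloid cells, CD4 T cells, NK and innate lymphocytes and erythroid and stromal cells, zinc finger genes and T cell receptor variable segments. Each was tested with camera in limma with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. With an estimated correlation 0 of 33 lists passed in either experiment. With 2 libraries per group that version could hardly call any list, so a failure there decides little either way. With blockade, DNA replication had 31 of 31 genes higher and an estimated correlation of -0.024, below the preset, yet an adjusted p of 0.318. Some called lists had estimates well above the preset, such as KAP1 heterochromatin in the knockout (0.29) and CD4 markers with blockade (0.40). For such lists the preset may make the p-value too small. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 30 in the knockout and 26 with blockade. Named genes were Trim28, Il2 and Il2ra, the 8 genes per direction with the largest fold change among called genes with separated replicates and at least 10 CPM (reads scaled to a common library total), up to 4 genes per list with the smallest adjusted p, and the top shared genes of the 2 comparisons. From each such set only the first few are given. Genes compared across experiments or at the Ly6, Setdb1 and Trim28 loci were chosen after their values were seen.

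Replicates were checked by a chi-square statistic per gene on recovered reads, where counting error alone gives about 1. Within groups it was 1.32 in untreated, 1.88 in control, 2.39 in knockout and 3.87 in blocked libraries, against 43.7 to 95.7 between groups. The test was tried on simulated data with 50 genes changed at each of 4 sizes, over 15303 and 13852 genes. In the knockout setting limma recovered 32%, 66%, 86% and 96% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and in the blockade setting 44%, 68%, 90% and 100%. Unchanged genes made up 6.67% and 6.21% of calls, and no call had the wrong sign. The simulation changed 200 genes, as many up as down, with known scaling and the spread of these libraries. It cannot show errors from scaling when many genes change, or from replicates that are only technical. Alternatives were DESeq2 1.42.0, edgeR 4.0.16 with TMM, RLE and upper-quartile scaling, TMM rescaling of the values, no filter, a strict filter at a mean of 5 CPM, pseudocounts of 0.5 and 5, a fold minimum of 2, protein-coding genes only, a fit of all 8 libraries, a replicate block and leaving out each library. With a library left out, its group holds a lone library, so the spread comes from the other group alone. Calls gained or lost in that setting may reflect that group's spread. Without a blocked library that group was untreated, whose statistic was 1.32 against 3.87. No scaling moved the median log2 fold change by as much as 0.07, but which direction held more calls changed with the scaling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.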

Results

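Trim28, which encodes a co-repressor that zinc finger proteins bring to chromatin, was the gene removed in the first experiment and was measured first in every library. Its normalised read count was 4262 and 4323 in the control libraries of activated CD8+ T cells with floxed Trim28, and 415 and 458 in the knockout libraries. The log2 fold change was -3.30 (SE 0.053, n = 2 per group), a 9.82-fold lower level. Il2, the gene of the T cell growth factor IL-2, fell from 9258 ± 58.2 to 5328 ± 116 (SD, n = 2), a log2 fold change of -0.80 (SE 0.027, adjusted p = 1.29e-05). Il2ra, the high-affinity IL-2 receptor chain, changed little, at -0.15 (SE 0.026), and did not pass without knockout replicate 2 (adjusted p = 0.0526).

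In the second experiment, an antibody against IL-2 was present during 3 days of stimulation through CD3 and CD28. Il2ra fell from 44153 ± 696 to 21981 ± 61.8 (SD, n = 2), a log2 fold change of -1.01 (SE 0.049). Il2 went from 16983 ± 344 to 18276 ± 623 and did not pass (log2 fold change 0.11, adjusted p = 0.0731). It passed in the same direction in the fit of all 8 libraries (adjusted p = 0.0379). Its log2 fold change was 0.071 without blocked replicate A and 0.14 without blocked replicate B. Trim28 was higher with the antibody, at 8227 ± 426 against 5847 ± 103 in untreated cells (log2 fold change 0.49, SE 0.051). Per library, the untreated values were 5774 and 5919.8 for Trim28, 17226 and 16739.7 for Il2, and 44645 and 43661 for Il2ra. The blocked libraries held 7926 and 8528, 18716 and 17835, and 22025 and 21937 in the same order. For the first experiment, the control libraries held 9299 and 9217 for Il2 and 26818 and 27387 for Il2ra, and the knockout libraries 5246 and 5410.2, then 24794 and 23967.

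**Figure D1:**
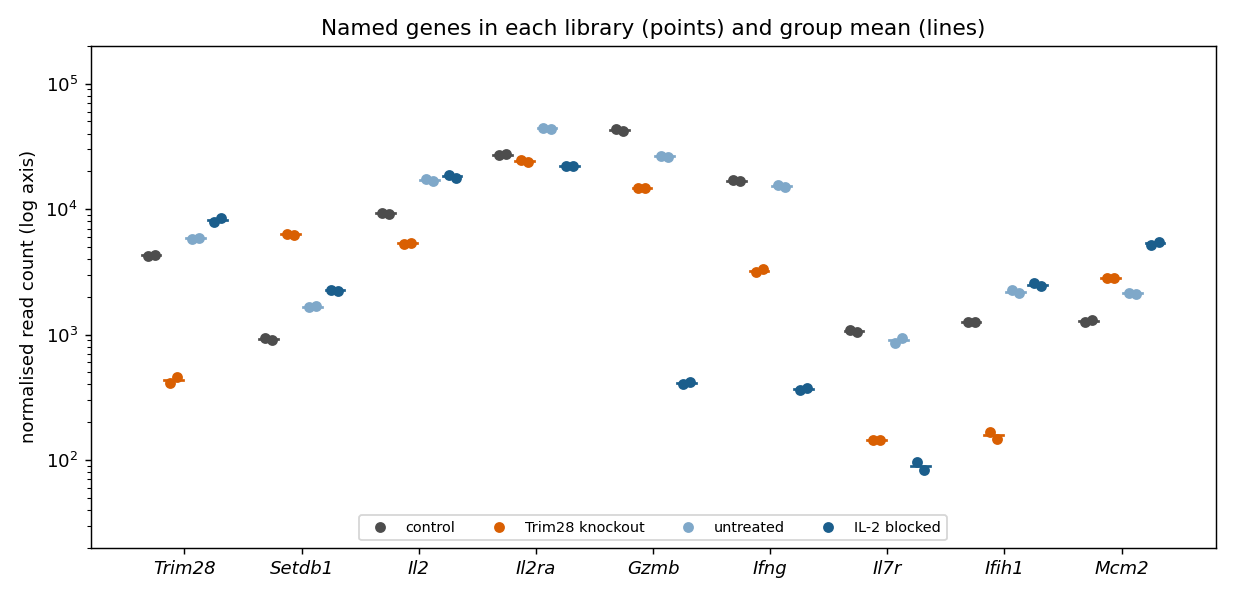
Normalised read counts (vertical axis, log scale) of 9 genes named in the text, with a point for each of the 8 libraries and a line at each group's mean (n = 2 per group). Trim28 fell in the knockout to a mean of 436, and of the plotted genes Gzmb and Ifng fell furthest with IL-2 blocked, to means of 410.0 and 368.

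Setdb1, the gene of the histone methyltransferase that acts with the TRIM28 protein, rose in the knockout from 926 ± 27.6 to 6297 ± 73 (SD, n = 2), a log2 fold change of 2.76 (SE 0.034, adjusted p = 1.82e-06). Reads of Gm37500, which overlaps its start on the other strand and also rose, could not be separated from it. The largest increases by the naming rule were in Pgpep1l, a peptidase-like gene (log2 fold change 5.92, SE 1.21), and M1ap, named for meiosis (4.47, SE 0.12). Next came the sulfotransferase gene Chst3 (3.91), the Src-family kinase gene Yes1 (3.80), Fam160a1 (3.77), the deubiquitinase gene Otud1 (3.71), the protease gene Ctse (3.52) and the guanylate-binding protein gene Gbp2b (3.48). Inhba, which encodes the activin A subunit, fell most by this rule, from 865 ± 34.8 to 43.2 ± 1.53 (log2 fold change -4.29, SE 0.07). The inducible heat shock genes Hspa1a and Hspa1b fell by a similar amount (-4.02 and -3.88), but they are near-identical copies that can share reads. They stood at 196 and 194 CPM in control and 12.2 and 13.3 CPM in knockout libraries. Untreated cells of the second experiment held only 1.92 and 4.75 CPM, and why the control level was so high was not tested. Next by this rule came Cfap54 (cilia, -3.67), Trim28 itself (-3.30), Gldc (glycine breakdown, -3.27) and Dnm1 (membrane fission, -3.25). In all, 5065 of 15415 tested genes rose and 4344 fell at an adjusted p under 0.05, of which 621 and 989 changed by at least 2-fold. Upper-quartile scaling called 4157 higher and 4951 lower, and the number that rose dropped to 3336 without knockout replicate 1 and to 3361 without knockout replicate 2. Pgpep1l lay at 8.11 ± 11.5 in the control, and its call was lost with DESeq2 (adjusted p = 0.0783), without a filter (0.104), without knockout replicate 1 (0.135) and without knockout replicate 2 (0.136).

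Several effector genes fell in the knockout. Ifng, the gene of interferon gamma, fell from 16792 ± 189 to 3232 ± 120.3 (SD, n = 2, log2 fold change -2.38, SE 0.032), and Gzmb, the gene of the killing protease granzyme B, from 42585 ± 1118 to 14846 ± 1.77 (-1.52, SE 0.025). The death ligand genes moved apart, with Fasl lower (-1.55) and Tnfsf10, which encodes TRAIL, higher (2.93). Among cytotoxic effector molecules 3 of 13 tested genes rose and 9 fell (4 and 9 adjusted over the list alone). Among cytokines and chemokines the counts were 8 and 16 of 27 (8 and 16 adjusted over the list alone), with Il16 higher (1.27) and the cytokine gene Lif lower (-1.22). Of the IL-2 and STAT5 targets, 9 rose and 14 fell of 30 (10 and 14 adjusted over the list alone), including Cish, a feedback inhibitor induced by STAT5 (-0.73, SE 0.024). None of these 3 lists passed against the other genes (camera, adjusted p = 0.052, 0.052 and 0.183). The cytotoxic list passed as lower without a filter (0.0372), over protein-coding genes (0.0495) and without knockout replicate 2 (adjusted p = 0.0471). The cytokine list passed as lower over protein-coding genes (0.0418), without control replicate 2 (0.0371) and without knockout replicate 2 (adjusted p = 0.0471).

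Genes of T cell state changed in both directions with the knockout. Il7r, the receptor for the survival cytokine IL-7, fell from 1063 ± 23.4 to 144 ± 0.234 (SD, n = 2, log2 fold change -2.88, SE 0.049), while Ccr7, a lymph node homing receptor gene, rose (0.77, SE 0.023). The naive and memory list had 11 higher and 13 lower of 29 genes (11 and 14 adjusted over the list alone, adjusted p = 0.309). Effector transcription factors split into 8 and 11 of 22 (8 and 11 adjusted over the list alone, adjusted p = 0.281), with Stat4, which relays IL-12 signals, lower (-1.08) and Stat5a, which relays IL-2 signals, higher (0.69). Inhibitory receptor and exhaustion genes split into 6 and 6 of 17 (6 and 6 adjusted over the list alone, adjusted p = 0.469), with Havcr2 (TIM-3) at -2.23, Pdcd1 (PD-1) at 0.77 and Btla at 0.50. Activation markers and nutrient receptors had 10 higher and 14 lower of 26 (11 and 14 adjusted over the list alone, adjusted p = 0.309), and included the inhibitory receptor gene Cd5 (0.92), the glutamine transporter gene Slc1a5 (-0.80) and the co-stimulator gene Icos (-0.92). Of 35 T cell receptor signalling genes, 17 rose and 15 fell (17 and 16 adjusted over the list alone, adjusted p = 0.985), among them Themis (-1.002) and Nfatc1 (-0.67). The median and mean of that list were above 0 while its test pointed down. For the IL-17 programme the counts were 4 and 4 of 10 (4 and 4 adjusted over the list alone, adjusted p = 0.588, median 0.038, mean -0.025), and the chemokine receptor gene Ccr6 rose (2.85). The median of that list was 0.37 and 0.66 without control replicate 1 or 2, 0.69 with the strict filter and -0.14 without a filter. At the Il2 locus, 3 of 13 genes rose and 8 fell (3 and 8 adjusted over the list alone, adjusted p = 0.19). 4932438A13Rik beside Il2 fell (-1.20, SE 0.034), the cyclin gene Ccna2 rose (0.76), and Fgf2, a growth factor gene, went from 5.58 ± 2.15 to 97.7 ± 10.1.

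Most listed genes of the cell cycle and of ribosome assembly rose in the knockout. Mcm2, part of the replicative helicase, rose from 1279 ± 33.2 to 2822 ± 31.9 (SD, n = 2, log2 fold change 1.14, SE 0.034), and Rrm2, which supplies nucleotides, by 1.05 (SE 0.033). DNA replication genes had 29 of 31 higher and 0 lower (29 and 0 adjusted over the list alone, adjusted p = 3.8e-09 by camera, adjusted p = 0.424 with an estimated correlation). Mitosis genes had 21 higher and 2 lower of 28 (21 and 2 adjusted over the list alone, adjusted p = 3.56e-05, and 0.501 with an estimated correlation), including Cenpa, a centromeric histone gene (0.66). Of 25 ribosome biogenesis genes 20 rose and 2 fell (20 and 2 adjusted over the list alone, adjusted p = 7.33e-05, and 0.424 with an estimated correlation), with Noc2l at 0.54 and Bop1 at 0.51. The respiratory chain list had 13 higher, 2 lower and 13 not passing (13 and 2 adjusted over the list alone, adjusted p = 0.0388, and 0.692 with an estimated correlation), with Sdha at 0.66 and Atp5a1 at 0.42. That call was lost after TMM rescaling (adjusted p = 0.0557), over protein-coding genes (0.0806), with the strict filter (0.0842), without control replicate 2 (0.13) and without knockout replicate 2 (0.121).

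Genes of sugar metabolism and stress changed in both directions in the knockout. The glucose transporter gene Slc2a3 fell from 5108 ± 228 to 1823 ± 5.28 (SD, n = 2, log2 fold change -1.49, SE 0.038), with Bnip3 (-1.50), a hypoxia-induced mitophagy gene, and the aldolase gene Aldoc (-1.48). Glycolysis genes had 4 higher and 14 lower of 23 (4 and 14 adjusted over the list alone, adjusted p = 0.00747, and 0.501 with an estimated correlation). Immediate early and heat shock genes had 5 higher and 18 lower of 25 (6 and 19 adjusted over the list alone, adjusted p = 8.37e-05, and 0.501 with an estimated correlation). Among p53 targets 4 rose and 9 fell of 19 (4 and 9 adjusted over the list alone, adjusted p = 0.0388, and 0.501 with an estimated correlation), including Cdkn1a, a cell cycle inhibitor gene (-1.73, SE 0.029), and the kinase gene Plk2 (-1.84). The p53 call was lost without knockout replicate 1 (adjusted p = 0.0653) and without knockout replicate 2 (0.0656). Cholesterol synthesis genes (6 higher, 10 lower of 22; 6 and 10 adjusted over the list alone) did not pass (adjusted p = 0.19). Amino acid stress genes (13 higher, 6 lower of 21; 13 and 6 adjusted over the list alone) did not pass either (adjusted p = 0.23, median 0.29, mean -0.075), and the serine-glycine enzyme gene Shmt2 rose (0.73). Regulators of apoptosis had 11 higher and 6 lower of 20 (11 and 6 adjusted over the list alone, adjusted p = 0.548), with the death gene Bid (1.60) and the survival gene Bcl2l1 (0.81) both higher and the death gene Bcl2l11 lower (-0.85).

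Most interferon-stimulated genes fell when Trim28 was lost. Ifih1, the gene of the double-stranded RNA sensor MDA5, fell from 1252 ± 0.502 to 157 ± 13 (SD, n = 2, log2 fold change -2.99, SE 0.067). Trim30a (-1.59) and Ifi27l2a (-1.43) also fell. They were named for their adjusted p, and other members, such as Mx2 (-5.21), fell further. Of 30 genes 27 fell and 1 rose (1 and 27 adjusted over the list alone), with a median log2 fold change of -1.49. The list passed by camera (adjusted p = 1.45e-09) but not with an estimated correlation (adjusted p = 0.424).

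Chromatin regulators of the TRIM28 pathway mostly rose, with Trim28 itself the exception among those named. Besides Setdb1, the zinc finger gene Zfp445, which acts at imprinted loci, rose from 1692 ± 11.5 to 3126 ± 85.7 (SD, n = 2, log2 fold change 0.89). The KAP1 heterochromatin list had 22 higher and 5 lower of 29 (23 and 5 adjusted over the list alone, adjusted p = 0.00107, and 0.536 with an estimated correlation). Chromatin loop proteins had 13 higher and 6 lower of 22 (14 and 6 adjusted over the list alone, adjusted p = 0.222), with the boundary protein gene Ctcf higher (0.59, SE 0.036). Zinc finger genes, whose proteins include those that recruit TRIM28, had 102 higher, 70 lower and 125 not passing (101 and 70 adjusted over the list alone, adjusted p = 0.548), and Zfp420 rose (1.36). Imprinted genes had 5 higher and 6 lower of 23 (4 and 6 adjusted over the list alone, adjusted p = 0.548), with Plagl1 lower (-1.79). Germline genes had 1 higher and 6 lower of 8 (1 and 6 adjusted over the list alone, adjusted p = 0.177). The piRNA pathway gene Tdrd9, listed at 0 in both control libraries, reached 39.8 ± 0.567, while Brdt (-2.14) and Tex15 (-0.52) fell. The germline list passed as lower without knockout replicate 1 (adjusted p = 0.0273) and without knockout replicate 2 (0.0281), while fry called it the other way, as higher (adjusted p = 0.00216).

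Neighbouring genes of the Ly6 family on chromosome 15, which encode small surface proteins, moved in opposite directions in the knockout and were picked out after their values were seen. Ly6d was listed at 0 in both control libraries and reached 79.1 ± 10.7 (SD, n = 2) in the knockout, and Ly6k rose from 23.8 ± 3.58 to 179 ± 15.2 (log2 fold change 2.87, SE 0.14). Ly6e rose by 0.55. Farther along the cluster, Ly6a fell from 1345 ± 63.6 to 193 ± 18.1 (log2 fold change -2.80, SE 0.076), the log2 fold changes of Ly6c1 and Ly6c2 were -1.999 and -2.02, and Ly6i went from 14.2 ± 2.86 to listed at 0. All 7 tested genes between positions 74762056 and 75111970 were called, 3 higher and 4 lower.

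**Figure D2:**
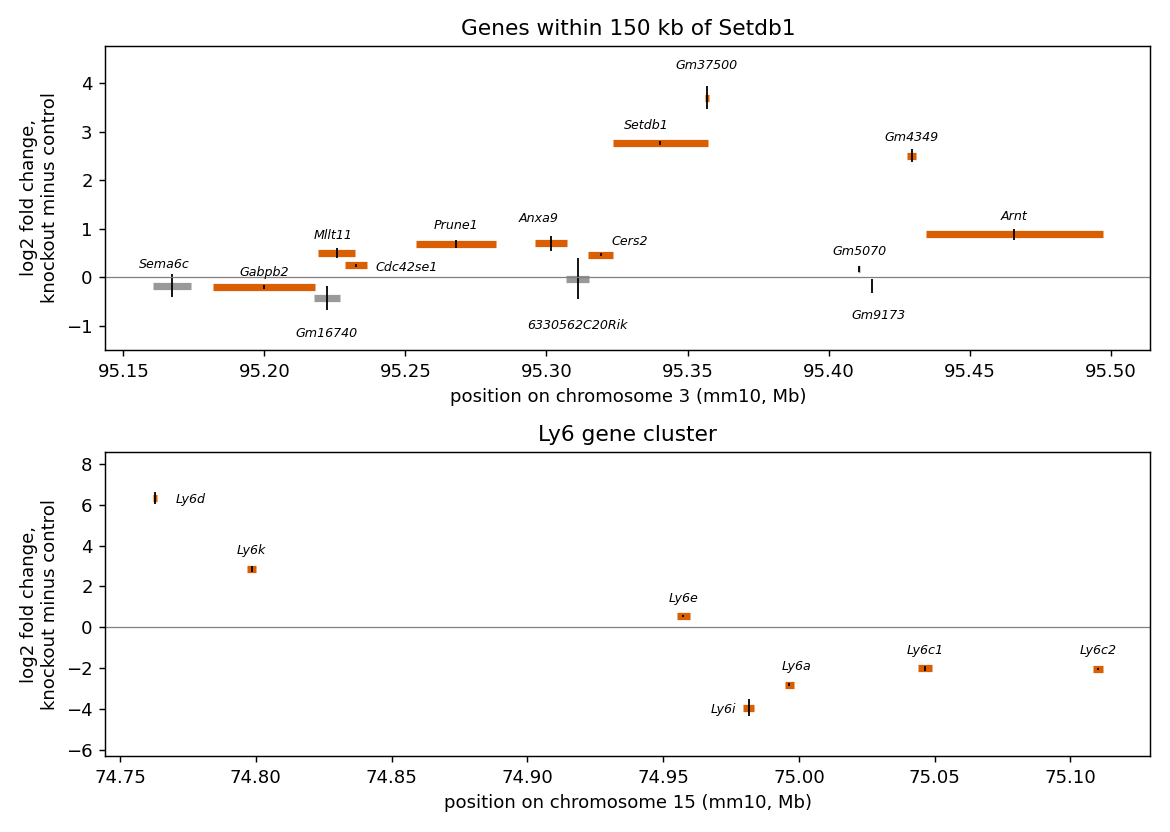
Log2 fold change in the knockout (vertical axis, log2 of value + 1, error bars SE, n = 2 per group) against position in megabases of the tested genes within 150 kb of Setdb1 and in the Ly6 cluster, with bars spanning each gene and called genes in orange. Setdb1 lies at 2.76, and Ly6d, listed at 0 in the control, is drawn on the same scale.

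Markers of other cell types moved in different directions. The NK receptor genes Klrc1, Klrd1 and Klrk1, which activated CD8+ T cells also express, fell, with log2 fold changes of -2.39, -2.75 and -3.16. Their list had 2 higher and 5 lower of 8 (2 and 5 adjusted over the list alone, adjusted p = 0.0388, and 0.501 with an estimated correlation). The NK list was not called after TMM rescaling (adjusted p = 0.0557), without a filter (0.468) or without control replicate 1 (0.0582). Of 10 B cell markers 3 rose and 4 fell (3 and 4 adjusted over the list alone, adjusted p = 0.68), with the antigen presentation gene H2-Ab1 lower (-1.65) and the antibody heavy chain gene Ighm higher (0.46). Myeloid markers had 0 higher and 2 lower of 6 (0 and 2 adjusted over the list alone, adjusted p = 0.175), with Cd68 at -0.76. CD4 T cell markers had 3 higher and 5 lower of 8 (3 and 5 adjusted over the list alone, adjusted p = 0.137), and Cd40lg, the gene of the helper ligand CD40L, fell from 355 ± 13.5 to 45.2 ± 5.41. The CD4 list passed as lower with the strict filter (0.00465) and without knockout replicate 2 (adjusted p = 0.049). Of 5 erythroid and stromal markers 1 rose, Pecam1 (0.93), and 0 fell (1 and 0 adjusted over the list alone, adjusted p = 0.985, median -0.41, while the test pointed up). Their median was -0.99 without control replicate 1, where the test pointed down, and 0.39 without control replicate 2. Mitochondrially encoded genes split into 5 higher and 8 lower of 15 (5 and 8 adjusted over the list alone, adjusted p = 0.181), with mt-Co1 lower (-0.96). They passed as lower without control replicate 2 (adjusted p = 0.0371). T cell receptor variable segments, which follow the clones present, had 30 higher and 3 lower of 104 (24 and 3 adjusted over the list alone, adjusted p = 0.0182, and 0.461 with an estimated correlation), such as Trbv13-2 (0.60). Their call was lost with the strict filter (adjusted p = 0.411), without control replicate 1 (0.0806) and without control replicate 2 (0.0658).

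The genes of granzyme B and interferon gamma were among those that IL-2 blockade lowered most. Gzmb fell from 26290.4 ± 556 to 410.0 ± 7.42 (SD, n = 2, log2 fold change -6.00, SE 0.051) and Ifng from 15344 ± 445 to 368 ± 9.32 (-5.38, SE 0.054). By the naming rule, the other largest decreases were in the nucleoside enzyme gene Upp1 (-6.62), Fhdc1 (-5.56), the glycogen enzyme gene Pygl (-5.16) and Plac8 (-5.15). The largest increases were in the integrin gene Itga9 (4.85, SE 0.18), the B cell transcription factor gene Spib (4.66, SE 0.26), the ion channel gene Trpa1 (3.90), Fcrl1 (3.37) and the retinoid enzyme gene Dhrs3 (3.13). In all, 4391 of 13978 tested genes rose and 4033 fell at an adjusted p under 0.05, of which 679 and 1402 changed by at least 2-fold.

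Most IL-2 and STAT5 targets fell with blockade. Cish fell from 6577 ± 8.25 to 751 ± 10.6 (SD, n = 2, log2 fold change -3.13, SE 0.053), and 23 of 29 list members fell while 5 rose (5 and 23 adjusted over the list alone, adjusted p = 2.02e-09, and 0.364 with an estimated correlation). Cytotoxic molecules had 10 lower and 1 higher of 12 (1 and 10 adjusted over the list alone, adjusted p = 1.14e-05, and 0.318 with an estimated correlation), among them the pore-forming protein gene Prf1 (-2.36). Of 26 cytokine and chemokine genes 2 rose and 23 fell (3 and 23 adjusted over the list alone, adjusted p = 8.85e-11, and 0.352 with an estimated correlation), with Ccl3 at -2.85, Ccl4 at -2.15 and lymphotoxin gene Lta at -2.34. Effector transcription factors had 3 higher and 16 lower of 21 (4 and 16 adjusted over the list alone, adjusted p = 3.35e-06, and 0.328 with an estimated correlation), including Ikzf3 (-1.80), Id2 (-2.14) and the T-bet gene Tbx21 (-1.65). Inhibitory receptor genes had 3 higher and 12 lower of 17 (4 and 12 adjusted over the list alone, adjusted p = 0.00118, and 0.352 with an estimated correlation), with Ctla4 lower (-1.12) and Btla higher (1.51). T cell receptor signalling genes had 9 higher and 24 lower of 35 (9 and 24 adjusted over the list alone, adjusted p = 0.000105, and 0.418 with an estimated correlation), with the ubiquitin ligase gene Cblb at -1.46 and Malt1 at -1.34.

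Naive and memory genes split with blockade, with Actn1 higher (1.90, SE 0.052), Ly6c2, a surface protein of memory CD8+ cells, lower (-3.25) and Il7r lower (-3.32). They had 8 higher and 15 lower of 29 (8 and 15 adjusted over the list alone, adjusted p = 0.178). Activation markers and nutrient receptors had 11 higher and 14 lower of 26 (11 and 14 adjusted over the list alone, adjusted p = 0.0687), with the co-stimulator gene Tnfrsf9 at -1.84 and Cd2 at -1.81. That list passed as lower with the strict filter (adjusted p = 0.0269). Its median was -0.21 in the main fit, -0.18 without blocked replicate A and -0.31 without blocked replicate B. It was -0.19 without untreated replicate 1 and -0.19 without untreated replicate 2. The IL-17 programme had 6 higher and 2 lower of 10 (6 and 2 adjusted over the list alone, adjusted p = 0.158, and 0.0406, as higher, without untreated replicate 1), and the chemokine gene Ccl20 fell (-4.32). Il2 locus neighbours had 6 higher and 5 lower of 13 (6 and 5 adjusted over the list alone, adjusted p = 0.998, median 0.18, mean -0.14, and a median of 0.31 without untreated replicate 1), with 4932438A13Rik at -1.07 and Fgf2 at 1.16. Interferon-stimulated genes had 4 higher and 26 lower of 32 (4 and 26 adjusted over the list alone, adjusted p = 5.85e-09, and 0.318 with an estimated correlation), including Oas3 (-2.73) and Zbp1 (-2.40), both sensors of nucleic acids. Immediate early and heat shock genes had 2 higher and 19 lower of 25 (2 and 19 adjusted over the list alone, adjusted p = 3.73e-09, and 0.352 with an estimated correlation), with Egr2 at -1.96 and Atf3 at -2.36.

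Every tested DNA replication gene rose with blockade. Mcm2 went from 2133 ± 27.6 to 5321 ± 182 (SD, n = 2, log2 fold change 1.32, SE 0.051), Rrm1 rose by 1.24 and the ligase gene Lig1 by 1.28, and the list had 31 of 31 higher (31 and 0 adjusted over the list alone, adjusted p = 3.74e-17, and 0.318 with an estimated correlation). Mitosis genes had 25 higher and 2 lower of 28 (25 and 2 adjusted over the list alone, adjusted p = 5.26e-10, and 0.318 with an estimated correlation), with Ccna2 at 1.14 and the checkpoint kinase gene Bub1b at 1.28. The KAP1 heterochromatin list had 20 higher and 3 lower of 29 (20 and 3 adjusted over the list alone, adjusted p = 0.000188, and 0.418 with an estimated correlation), with the heterochromatin protein gene Cbx5 at 1.51 and the DNA methyltransferase gene Dnmt1 at 1.17. Chromatin loop proteins had 12 higher and 2 lower of 22 (12 and 2 adjusted over the list alone, adjusted p = 0.00486, and 0.364 with an estimated correlation), including the cohesin genes Cdca5 (1.01) and Smc1a (0.65). Ribosome biogenesis genes had 10 higher and 3 lower of 25 (10 and 2 adjusted over the list alone, adjusted p = 0.158, and 0.0206, as higher, without a filter), with Utp20 at 0.63.

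Metabolic genes moved in both directions with blockade. Aldoc fell from 1573 ± 78.9 to 67 ± 6.98 (SD, n = 2, log2 fold change -4.54, SE 0.10) and Slc2a3 also fell (-2.04). Glycolysis genes had 5 higher and 13 lower of 23 (5 and 13 adjusted over the list alone, adjusted p = 0.000476, and 0.429 with an estimated correlation). The respiratory chain list had 13 higher and 1 lower of 28 (12 and 1 adjusted over the list alone, adjusted p = 0.0135, and 0.467 with an estimated correlation), with Ndufa4 at 0.88. Its call was lost with the strict filter (adjusted p = 0.062) and without blocked replicate B (0.0587), untreated replicate 1 (0.129) or untreated replicate 2 (0.183). Cholesterol genes had 3 higher and 14 lower of 23 (3 and 14 adjusted over the list alone, adjusted p = 0.0162, and 0.418 with an estimated correlation). That list was not called without blocked replicate A (adjusted p = 0.07), blocked replicate B (0.091), untreated replicate 1 (0.122) or untreated replicate 2 (0.0646). Amino acid stress genes (10 higher, 8 lower of 21; 11 and 8 adjusted over the list alone, adjusted p = 0.712, median 0.17, mean -0.19, and medians of 0.27 with the strict filter and 0.0073 over protein-coding genes) included Sesn2, a stress-induced gene (-1.02). Regulators of apoptosis (5 higher, 12 lower of 20; 5 and 12 adjusted over the list alone, adjusted p = 0.351) did not pass as a group, with Bid at 0.94 and Bcl2l11 at -0.72. Of 19 p53 targets 10 rose and 8 fell (10 and 8 adjusted over the list alone, adjusted p = 0.857, median 0.33, mean -0.089, and a median of 0.067 without a filter), with Plk2 at -1.75 and Cdkn1a at -1.76. The median of the p53 list stayed above 0 without blocked replicate A (0.27) and without blocked replicate B (0.36).

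Markers of other cell types also changed with blockade. Klrk1, Klrc1 and Klrd1 had log2 fold changes of -2.78, -3.14 and -2.66, and the NK list had 0 higher and 5 lower of 6 (0 and 5 adjusted over the list alone, adjusted p = 8.05e-05, and 0.364 with an estimated correlation). B cell markers had 4 higher and 2 lower of 11 (4 and 2 adjusted over the list alone, adjusted p = 0.266), with H2-Ab1 lower (-4.96) and Spib and Ighm higher (4.66 and 0.55). CD4 T cell markers had 1 higher and 6 lower of 8 (1 and 6 adjusted over the list alone, adjusted p = 0.0039, and 0.418 with an estimated correlation), including Icos (-1.78). Myeloid markers had 0 higher and 3 lower of 4 (0 and 3 adjusted over the list alone, adjusted p = 0.0237, and 0.364 with an estimated correlation), with Cd68 at -2.25 and Mpeg1 at -2.81. The myeloid call was lost without a filter (adjusted p = 0.293), without blocked replicate A (0.124) and without blocked replicate B (0.112). Erythroid and stromal markers had 5 higher and 0 lower of 6 (5 and 0 adjusted over the list alone, adjusted p = 0.0711, and 0.0171, as higher, without untreated replicate 2), with Pecam1 at 1.03. Mitochondrially encoded genes split into 5 and 5 of 15 (5 and 5 adjusted over the list alone, adjusted p = 0.583), with mt-Rnr1 at -1.99. Their median was 0.21 without blocked replicate A and -0.12 without blocked replicate B. Zinc finger genes had 74 higher and 60 lower of 294 (72 and 58 adjusted over the list alone, adjusted p = 0.712), with Zfp362 at 2.56. Imprinted genes (4 higher, 7 lower of 22; 4 and 7 adjusted over the list alone, adjusted p = 0.461) included Igf2r at -0.57. Germline genes (2 higher, 4 lower of 7; 2 and 4 adjusted over the list alone, adjusted p = 0.316) included Brdt at -2.04. T cell receptor variable segments (10 higher, 3 lower of 67; 3 and 1 adjusted over the list alone, adjusted p = 0.262) included Trbv16 at 0.64, and their list passed as higher without a filter (0.0343).

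**Figure D3:**
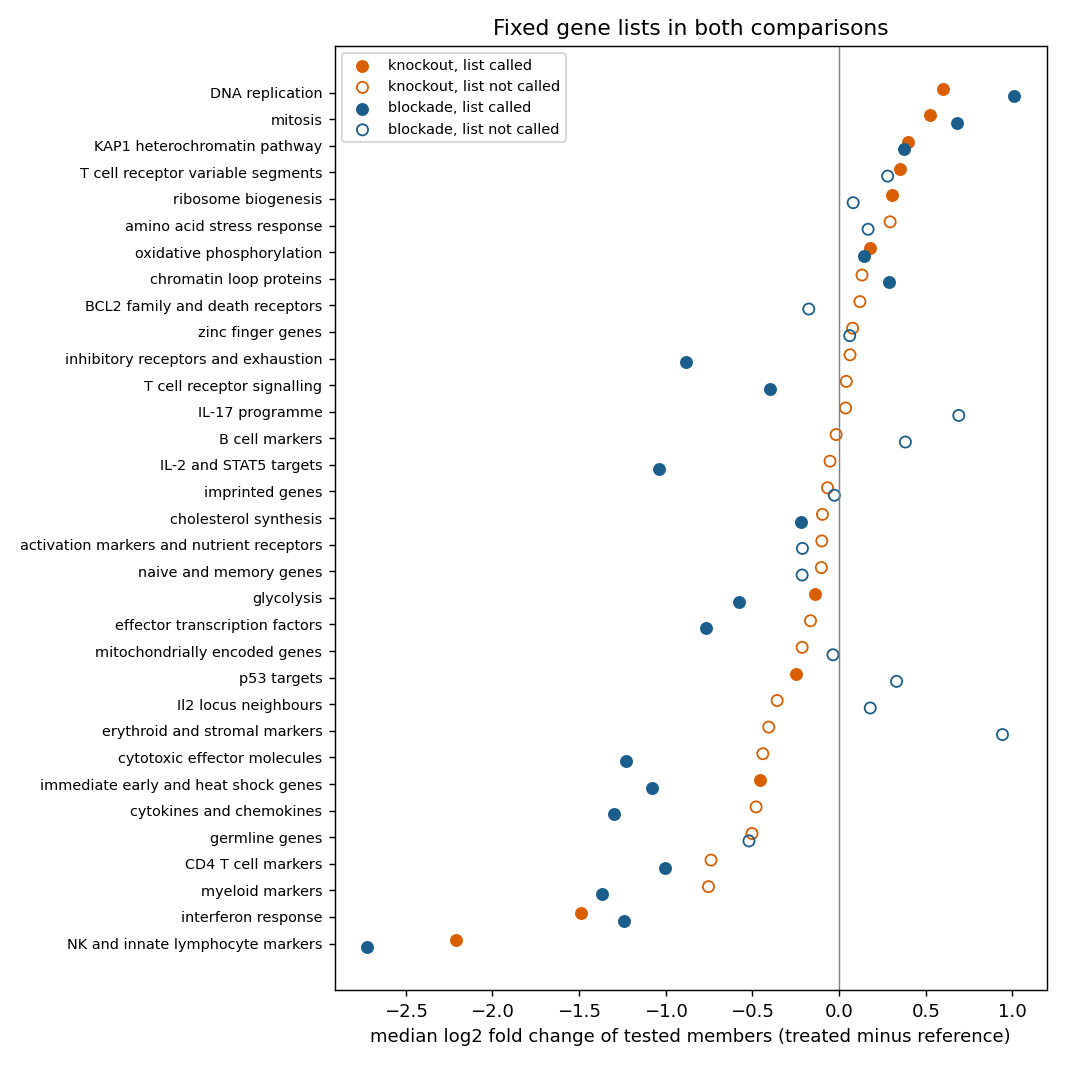
Median log2 fold change (horizontal axis, treated minus reference) of the tested members of 33 fixed gene lists, with a point per comparison, filled where the list passed by camera with its preset correlation. DNA replication genes lie highest in both comparisons (0.60 and 1.01), and interferon response genes lie at -1.49 and -1.24.

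Many genes changed the same way in both experiments. Among those lower in both were the guanylate-binding protein gene Gbp2 (log2 fold change -2.47 in the knockout, SE 0.033, and -2.24 with blockade, SE 0.048, n = 2 per group), Hspa1b (-3.88 and -2.29), Ifng (-2.38 and -5.38) and Cdkn1a (-1.73 and -1.76). Higher in both were Otud1 (3.71 and 1.97), Setdb1 (2.76 and 0.43), the actin gene Actb (1.14 and 0.50) and the adaptor gene Apbb1ip (2.27 and 1.10). Opposite changes were seen in Gbp2b (3.48 and -2.54), Trim28, Ccr7 (0.77 and -0.41) and the polymerase I factor gene Taf1c (1.27 and -0.45). Of 12428 genes tested in both experiments, 2255 were lower in both, against 1053 if the calls were independent (odds ratio 9.05). A further 2802 were higher in both (1493 if independent, odds ratio 8.32), and 695 were called in opposite directions (2515 if independent). The number in opposite directions was 406 without knockout replicate 1 and 406 without knockout replicate 2. Across these genes, which are not independent replicates, log2 fold changes had a Pearson r of 0.600 and a Spearman rho of 0.612.

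**Figure D4:**
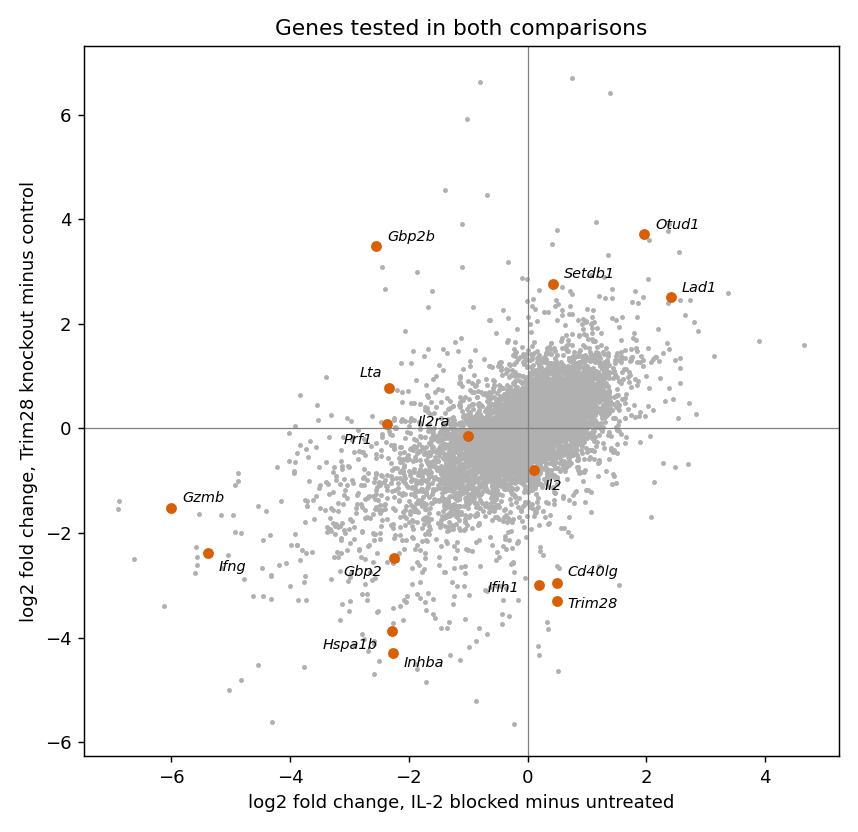
Log2 fold change of each of 12428 genes with IL-2 blocked (horizontal axis) and in the Trim28 knockout (vertical axis), with a grey point per gene and named genes in orange. Gzmb lies at -6.00 and -1.52, and Gbp2b at -2.54 and 3.48.

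The knockout and blockade effects were also compared directly, as the knockout log2 fold change minus the blockade log2 fold change in a fit of all 8 libraries. Gzmb differed by 4.48 (SE 0.047, adjusted p = 6.85e-09) and Ifng by 3.00 (SE 0.055, adjusted p = 1.75e-07), since both fell further with blockade. Lta, which rose in the knockout (0.77) and fell with blockade (-2.34), differed by 3.10 (SE 0.10). Prf1 did not pass in the knockout (log2 fold change 0.085, adjusted p = 0.061, and 0.0488 over protein-coding genes) and differed by 2.45 (SE 0.049). Il2 and Cd40lg, lower in the knockout but not with blockade, differed by -0.90 (SE 0.051) and -3.44 (SE 0.16), and Setdb1 by 2.33 (SE 0.05). Of 15460 genes tested in this way, 4996 differed at an adjusted p under 0.05, 2945 with a positive and 2051 with a negative difference. Only 12428 genes had passed the filter in both experiments fitted alone. For the rest, a difference can reflect little expression in the other experiment, as for Tdrd9 (5.35, with 0 for blockade).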

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

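EdgeR with TMM had been planned as the main test and became an alternative once the deposited values proved to be scaled. Limma as the reported test was thus chosen after the data were seen. Alternatives that used TMM rescaling, other pseudocounts or protein-coding genes only were also chosen after seeing the data. In the knockout, 2139 of 2173 values of named genes kept their direction and side of the threshold, 25 lost the call, 9 gained it and 0 changed direction. With blockade, 1825 of 1864 did, 28 lost it, 11 gained it and 0 changed direction. DESeq2 called 2709 genes lower in the knockout. It placed 1474 genes lower in both comparisons and 323 in opposite directions, with r at 0.516. The balance of higher and lower calls in the knockout turned with the scaling, from 5065 and 4344 as deposited to 4548 and 4571 with edgeR TMM, 4543 and 4582 with RLE, 4157 and 4951 with upper-quartile scaling and 4670 and 4707 after TMM rescaling. With blockade the same 4 settings gave 4258 and 4151, 4242 and 4254, 4223 and 4253, and 4205 and 4109. The authors' table held 6189 and 6077 called genes. A fold of at least 2, which by construction calls fewer genes, left 621 higher and 989 lower in the knockout and 679 and 1402 with blockade. It left 519 genes lower in both, 180 higher in both and 32 opposite. The strict filter raised r to 0.662 and rho to 0.650, and for this and DESeq2 the cause was not tested. With an estimated correlation, where 2 libraries per group left the test hardly able to call any list, 0 lists passed in either direction in either comparison. Fry called 13 lists higher and 17 lower in the knockout and 8 higher and 18 lower with blockade, since it does not compare a list with other genes. Leaving out each library in turn, the lone sample being assumed to vary like the other group, gave 3336 to 4704 genes higher in the knockout. It gave 4 to 8 lists lower in the knockout and 406 to 871 genes in opposite directions. The knockout and control numbers did not pair their libraries (r = -0.20 between the 2 numbered differences over 10337 genes). A replicate block called 4881 higher and 4197 lower, 4798 and 4083 of them shared with the reported calls. For blockade, no paired analysis was possible because the table columns of the 2 blocked libraries do not show which is replicate 1 and which is replicate 2, so the planned block was not run there. A depth of 13222831 to 17069569 reads limits what can be said of genes under a value of 10, which were not tested.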

Other observations

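The zinc finger genes Zfp324 and Zfp128 beside Trim28 rose in the knockout, where Trim28 fell, and with blockade, where Trim28 rose. Zfp324 had log2 fold changes of 1.59 (SE 0.13) and 1.23 (SE 0.18), with a difference of 0.36 that did not pass (adjusted p = 0.327). For Zfp128 they were 1.53 (SE 0.14) and 0.57 (SE 0.22), with a difference of 0.96 (adjusted p = 0.0186). The blockade call of Zfp128 was lost with DESeq2 (adjusted p = 0.305), without a filter (0.0602) and without blocked replicate A (0.0942), blocked replicate B (0.0542) or untreated replicate 2 (0.128). Other genes at this locus went differently, with Zfp110 (0.88 and -0.094) and Zbtb45 (0.79 and 0.15) called in the knockout and not with blockade. Zbtb45 lies within the annotated span of Trim28 on the other strand, so reads of these 2 genes could not be separated. Within 150 kb, Trim28 included, 7 of 13 tested genes rose in the knockout and 3 fell. On chromosome 5, 15 of 16 tested genes between positions 10242041 and 11922821 fell at least 2-fold. Their values lay close together, and whether these genes share reads was not tested. Of genes on the NK list, Ncr1 and Tyrobp were listed at 0 in all 4 libraries of the knockout experiment, and Klrb1c and Fcer1g did not exceed 8.11. Tyrobp and Fcer1g are also on the myeloid list.

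Of the tests below, only the removal of GC content, gene length and expression level trends was written down before its result was seen. Those that set the knockout against blockade compare separate experiments whose reference cells differed, with Hspa1a at 196 CPM in control and 1.92 CPM in untreated cells. Part of a difference between effects may come from that, which the SE does not cover. Fold changes of the knockout and of blockade ran together across genes (r = 0.600). Trends with GC content, gene length and expression level do not account for it, with r at 0.596 after their removal (12402 genes). Over 10212 protein-coding genes that no pseudogene is named after, r was 0.615. Many pseudogenes, such as Gm5070, carry names of their own, so this filter cannot exclude reads shared with those. Of 509 genes changed at least 2-fold in the knockout (reference means of at least 100, Trim28 left out), 64 had a knockout effect beyond that of blockade. The excess was over 2-fold after 2 SE (12.6%, exact 95% interval 9.82% to 15.8%, genes counted as independent), and 23 were called in the opposite direction with blockade. They argue against the knockout acting as a weaker IL-2 blockade and nothing else, as far as cells of both experiments would respond alike to less IL-2. This test replaced earlier ones on the share of genes in opposite directions, which did not decide together, at 12.1% of 5752 genes called in both comparisons (11.3% to 12.95%), 4.38% of 731 changed at least 2-fold in both (3.01% to 6.12%) and 6.19% of 1179 lowered at least 2-fold by blockade (4.88% to 7.72%). Less IL-2 may still account for part of the shared change, and a shared difference in growth or activation stays open.

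Setdb1 rose by 2.76 in the knockout. A wider altered chromosome segment that moved its neighbours as far is argued against by the other 41 tested genes within 0.5 Mb, with a median of 0.18 (SD 0.88). Within 150 kb, 8 of the other 14 rose and 1 fell (median 0.36, SD 1.14), and of these Gm37500, which overlaps the start of Setdb1 on the other strand, rose from 2.03 to 38.3, and Gm4349 from 14.2 to 85.5 (means, n = 2). The lowest value over 6 scalings was 2.70. None of them moved the median log2 fold change by as much as 0.07, so this check could hardly have gone otherwise. The effect exceeded that of blockade by 2.33 (SE 0.05). That excess argues against less IL-2 as the cause, as far as cells of both experiments would respond alike. A response to the loss of the TRIM28 protein may underlie the rise, while a smaller local change that reaches the nearest genes stays open and a strain or transgene difference near Setdb1 was not tested.

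Most interferon-stimulated genes fell in the knockout. Less interferon gamma as the cause of the whole fall would predict a smaller fall than with blockade, under which Ifng fell further. By the test of the difference, 10 of 30 genes fell further in the knockout and 8 differed the other way. The 10 argue against that cause of the whole fall, as far as cells of both experiments would respond alike. Ifih1 was among the 10, at -2.99 against 0.19 with blockade, where its call was lost without a filter (adjusted p = 0.0747) and without untreated replicate 2 (0.187). Loss of B cells carrying these transcripts stays open, since the 10 tested B cell markers did not move together. Of them 4 fell, among them H2-Ab1 (-1.65), and 3 rose, among them Ighm (0.46). An earlier test that this one replaced had used Ighm alone. Summed over the B cell list, the level was 250 CPM in control and 271 CPM in knockout libraries, a total that did not fall. For the other genes less interferon gamma may contribute, and less type I interferon signalling was not tested.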
